A study of Caenorhabditis elegans with 2 samples.

How the data were processed

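Chromatin immunoprecipitation followed by sequencing (ChIP-seq) was carried out on whole young adult Caenorhabditis elegans, per the labels, with an antibody against green fluorescent protein. The strain carries an EGFP and FLAG tag inserted by genome editing at bed-2 on chromosome III. The labels give 1 group of 2 biological replicates, each at an age of 63 hours, after sonication of the chromatin. The files used were 8 peak lists on assembly ce11, of which 4 belong to the series and 4 to single replicates. No second group was present, so no comparison between conditions was made. The input control that the submitters name was not analysed here.

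The deposited lists were made by the authors. Per the text deposited beside the samples, each replicate list derives from that replicate's alignment and a control, and the series lists derive from the alignments of both replicates. The aligner and the peak caller are not given in the sources used here. The irreproducible discovery rate (IDR) compares the ranks of peaks in 2 lists and keeps those ranked alike. Each deposited peak carries a score that the authors derived from its global IDR, and the formula was checked on the values of 100% of the rows of a ranked list within a tolerance of 1. Ranked lists also hold the −log10 of the global IDR as deposited. The lowest score in the thresholded lists is 830, the value the formula gives for a global IDR of 0.01. Each peak also has a signal value as the authors' peak caller gave it, and this is the authors' own value, used only to describe and rank peaks. The other deposited column used is the summit offset. Files hold no read counts, so the depth of each sample is unknown, and intervals cover counting error over peaks or genes only. In addition, 2 columns of matched-peak signal that could not be tied to the samples were not used. The matched-peak signal columns of the ranked list of true replicates entered 1 alternative, the correlation over all ranked peaks.

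The main set was the conservative list, made by comparing the true replicates. Peaks that overlapped by at least 1 base were merged into regions, each keeping the summit and signal of its strongest peak. The background was the merged set of ranked candidates that did not reach the threshold and overlapped no peak that did. Genes and transcript starts came from Ensembl release 115, and sequence came from the RefSeq genome of the same assembly. Each peak end was checked to lie inside the reference chromosome on the 6 chromosomes.

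Summits were placed in 7 classes in a fixed order, beginning with the promoter, defined as the 1000 bp upstream of a transcript start. A gene was called bound where a passing summit lay within 1000 bp of any of its transcript starts, and the tested genes were those with any ranked summit at that distance. Gene lists comprised 34 lists written before the data were examined and 11 gene biotypes, and those with at least 5 tested genes were used. Shares were compared with two-sided Fisher's exact tests with Benjamini-Hochberg adjustment at 0.05. Medians were compared with two-sided permutation tests of 100000 resamples, whose smallest possible p is 1e-05. Sequence words of 6 bases (6-mers, 2080 counting both strands as 1) were counted within 50 bp of summits. Their background held up to 10 candidates per region matched on GC decile and promoter class. Signal of each replicate in a region was the highest signal among overlapping peaks of that replicate's own ranked list. Intervals are 95% Clopper-Pearson intervals for shares and bootstrap intervals of 2000 resamples for correlations.

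Windows of 101 bp around summits were searched against the genome with blastn 2.17.0, and another copy was a hit of at least 50 bases and 80% identity elsewhere. Calculations used Python 3.11.15, numpy 2.4.6, pandas 2.3.3 and scipy 1.17.1, and plots used matplotlib 3.10.9.

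Scripts were tested on simulated data. With tRNA genes planted at 3 times their background share, the list test called them in 20 of 20 repeats, with a median odds ratio of 3.10. With nothing planted, it made 9 false calls of other lists over 20 repeats of 44 lists, 3 of them for piRNA genes. A test by random draws of summits made 0 such calls in 10 repeats. The k-mer test called a word planted in 10% of windows in 5 of 5 repeats. The permutation test of medians called 108 of 2000 simulated pairs with no difference and 1969 of 2000 with a shift of 0.5 SD.

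Named genes follow a rule fixed before the data were examined. It takes the 25 regions with the highest signal with the gene whose transcript start is nearest, and a divergent neighbour within 1000 bp. It adds peaks at bed-2, up to 4 bound genes of each list past the threshold, and the 3 regions at each end of the ratio between replicates. Alternatives covered the peak set, the IDR threshold, merging, promoter width, gene distance, background, k-mer length and window, and each replicate alone. A planned threshold of 0.01 coincided with the deposited one, so a threshold of 0.001 was added after seeing the data.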

Results

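Binding of the BED-2 protein was measured by ChIP-seq in whole young adult worms of 1 group with 2 biological replicates. The gene bed-2 encodes a protein with a BED-type zinc finger, a DNA-binding domain, and it was tagged with EGFP at its own locus. The labels give the target and stage and no further purpose. The question addressed here is where in the ce11 genome tagged BED-2 was detected and how alike the replicates were.

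The conservative list held 615 peaks, which merged to 566 regions. The optimal list held 626 peaks and does not contain the conservative one. Of the 615 conservative peaks, 512 (83.3%) overlapped a peak of the optimal list by at least 1 base. The list of replicate 1 alone held 238 peaks and that of replicate 2 alone held 256. Of the peaks of the conservative list, 94.3% were 320 bp wide, the maximum width, and 35 were narrower. Signal in the conservative list had a median of 85.3 and a maximum of 459. Depth is unknown, since the lists carry no read counts.

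The region with the highest signal lay upstream of mog-4 (WBGene00003392), which encodes a DEAH-box RNA helicase. It spanned II:14561748-14561988, with a signal of 458.8 in the pooled list, 222.2 in replicate 1 and 243.5 in replicate 2, and its summit was 266 bp upstream of the start. Next were 2 regions on chromosome IV near K08F11.1. The first, IV:4725483-4725714, had a signal of 443.6 and lay upstream of the non-coding RNA WBGene00195021. The second, IV:4727933-4728153, had a signal of 433.5 and lay 79 bp upstream of the pseudogene WBGene00023323. Then came the promoter of tasp-1 (III:10759155-10759370, signal 352.8), which encodes a taspase and is divergent from K01G5.10. A region at IV:9196319-9196516 had a signal of 328.3, with its summit 383 bp from the start of the non-coding RNA C46C2.12.

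Among the 25 regions with the highest signal, 21 were promoters, 3 were intergenic and 1 was intronic, in ccm-2. The nearest start was that of a protein-coding gene for 17 of them and of a pseudogene for 4. None was on the X chromosome (0 of 25). The promoters included that of rpa-2 (I:4769550-4769718, signal 319.6), a subunit of replication protein A, whose start is divergent from that of M04F3.7. They also included eel-1 (IV:3050379-3050584, signal 314.6), a HECT-type ubiquitin ligase, and the snoRNA F59C6.15 (I:10517150-10517321, signal 301.6). Signals of 295.1, 288.0 and 283.0 were found upstream of K12H4.5, mtcu-2 and dnj-28, the last divergent from supr-1. K10D2.5, divergent from the splicing factor gene prp-19, had 275.2. Promoters of F56G4.6 and wbp-4, which are divergent, shared a signal of 256.2, and Y62F5A.12 had 248.8. cnk-1 had 238.8, atad-3 with its divergent neighbour nrde-2 had 229.9, and pinn-1 had 227.6. The intronic region in ccm-2 (IV:1831228-1831547) had a signal of 227.4. Intergenic regions near the pseudogenes WBGene00014778, WBGene00023318 and WBGene00014975 had 281.0, 248.1 and 222.0.

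Passing summits lay mostly in promoters, which held 402 of 566 (71.0%, 95% interval 67.1 to 74.7) against 32.5% of 63737 candidates that did not pass. The odds ratio was 5.10 (Fisher's exact test, adjusted p = 9.39e-77). Bodies of non-coding RNA genes held 29 summits, 5.12% against 1.29% (odds ratio 4.14, adjusted p = 1.62e-09, Fisher's exact test). Coding exons held 4.24% against 26.4% (odds ratio 0.124, adjusted p = 1.21e-43) and introns 7.77% against 23.3% (odds ratio 0.277, adjusted p = 8.45e-22), by Fisher's exact test. Only 2 summits lay in 3′ UTRs (odds ratio 0.187, adjusted p = 0.00563, Fisher's exact test). Intergenic summits were at 10.6% against 13.5% (odds ratio 0.757, adjusted p = 0.0484, Fisher's exact test). The share in 5′ UTRs, 0.883% against 1.12%, did not pass (adjusted p = 0.839, Fisher's exact test). The intergenic difference did not pass with a promoter of 500 bp, among other alternatives, nor without replicate 1 (odds ratio 0.895), and without replicate 2 it turned direction (1.07). Nor did the 3′ UTR difference pass without replicate 1 (odds ratio 0.210) or at a global IDR of 0.001 (odds ratio 0, adjusted p = 0.0757, Fisher's exact test). Without replicate 2 the 3′ UTR odds ratio was 0. That of 5′ UTRs was 0 without replicate 1 and 0.788 without replicate 2. The odds ratio of coding exons was 0.0569 without replicate 1 and 0.0123 without replicate 2. Against the next 2000 candidates, a background chosen after seeing the data, neither the non-coding RNA class (odds ratio 1.53, adjusted p = 0.108) nor the 3′ UTR class (odds ratio 0.280, adjusted p = 0.117) passed by Fisher's exact test.

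**Figure D1:**
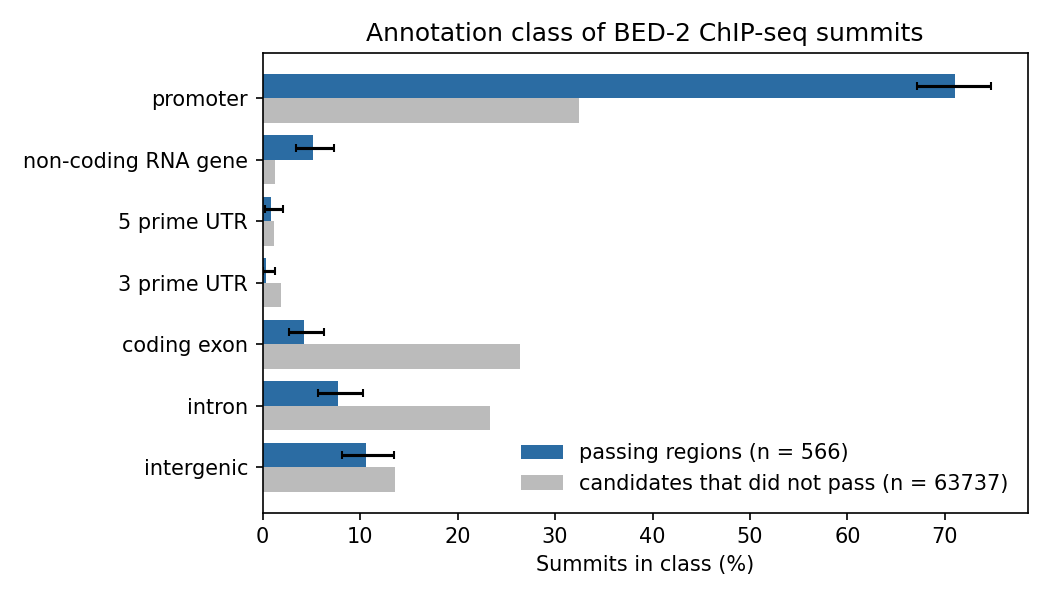
Share of summits in each annotation class, in percent, for the 566 passing regions (blue, bars from 0, with exact 95% intervals) and the 63737 candidates that did not pass (grey). Promoters held 71.0% of passing summits against 32.5% of the candidates, and coding exons 4.24% against 26.4%.

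The median distance from a passing summit to the nearest transcript start was 183 bp (quartiles 46.25 and 593.8), against 844 bp for candidates. The difference in medians was -661 bp, with a permutation p of 1e-05, the smallest that the resamples can give. To protein-coding starts the medians were 480 bp and 1233 bp. No chromosome departed from the candidates in its share of regions. Chromosome I held 19.1% against 15.1% (odds ratio 1.33, adjusted p = 0.0567) and chromosome V 17.7% against 21.3% (odds ratio 0.794, adjusted p = 0.117), by Fisher's exact test. Unadjusted, chromosomes I and V had p of 0.00944 and 0.0388 by Fisher's exact test. Chromosome I passed where peaks were not merged, and chromosome X at a global IDR of 0.001.

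Ribosomal protein genes and several classes of small non-coding RNA genes were bound more often than other genes. Of 77 tested ribosomal protein genes, 12 were bound (15.6%, 95% interval 8.32 to 25.6) against 2.94% of other genes, an odds ratio of 6.09. The adjusted p was 2.02e-05 by Fisher's exact test. The highest signals were at rpl-3 (III:3867502-3867664, 273.2), rpl-15 (IV:654852-655000, 264.1), rpl-35 (III:7854607-7854747, 243.1) and rps-24 (IV:385469-385636, 240.5). The summit lay 282 bp upstream of the start of rpl-3 and 343 bp upstream of that of rpl-15. Start sites of K11H12.8 and the pseudogene WBGene00020295 are divergent from those of rpl-15 and rps-24. Replicates had 102.7 and 169.1 at rpl-3 and 136.7 and 126.6 at rpl-15, for replicates 1 and 2. The list, written as a name pattern, missed rpl-7A, which was bound (IV:4390450-4390769, 85.3), and rpl-36.A. Another start was nearer to the summit for 7 of the 12, namely rps-23, rpl-20, rps-26, rps-19, rpl-43, rps-1 and rps-20. With rpl-7A and rpl-36.A added after seeing the data, 13 of 79 were bound (odds ratio 6.51).

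Among small RNA genes, 53 of 308 snoRNA genes, which guide RNA modification, were bound (17.2%, odds ratio 7.14, adjusted p = 4.93e-24, Fisher's exact test). Examples were F59C6.15 (301.6), K11H12.12 and K11H12.13, which share a peak with rpl-15 (264.1), and C51F7.3 (219.2). Peaks at snoRNA genes numbered 50, of which 3 were also within reach of a ribosomal protein gene. For tRNA genes the count was 75 of 578 (13.0%, odds ratio 5.21, adjusted p = 1.16e-25, Fisher's exact test), from 57 peaks. The tRNA odds ratio was 2.36 without replicate 2, 2.65 at a global IDR of 0.001 and 2.75 without peaks whose sequence recurs in the genome. The tRNA genes with the highest signal were WBGene00023221 (156.6), WBGene00023042 (124.8), and WBGene00023164 and WBGene00023165 at 1 peak (111.4). The first shares its peak with the snoRNA gene ZK994.7, whose start is 24 bp from the summit against 919 bp for the tRNA gene. Of 109 snRNA genes, 14 were bound (12.8%, odds ratio 4.87, adjusted p = 2.80e-05, Fisher's exact test). Spliced leader genes, which are annotated as snRNA genes, made up 6 of these, out of 21 tested (odds ratio 13.1, adjusted p = 1.38e-04, Fisher's exact test). Their highest signals were at sls-2.1 (175.9), sls-2.2 and sls-2.3 at 1 peak (133.1), and sls-2.15 (124.9). Without such recurring peaks the odds ratio was 0.878 for snRNA genes and 4.96 for spliced leader genes (adjusted p = 0.162, Fisher's exact test), and neither passed. Without replicates 1 and 2 the spliced leader odds ratio was 20.2 and 29.1, and without replicate 1 that of snRNA genes was 7.58.

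Chaperone and respiratory chain genes also passed. Heat shock protein genes were bound in 5 of 21 (odds ratio 10.3, adjusted p = 0.00153, Fisher's exact test). These were hsp-60 (189.9), the mitochondrial chaperonin, hsp-90 (189.4), hsp-1 (110.5), hsp-110 (107.5) and hsp-3 (101.7). The odds ratio was 22.3 without replicate 2. Other starts were nearer to 4 of these summits, Y22D7AL.10 at the hsp-60 peak, C47E8.4 at hsp-90, and the non-coding RNA genes F26D10.23 at hsp-1 and C30C11.14 at hsp-110. Respiratory chain genes were bound in 5 of 38 (odds ratio 4.97, adjusted p = 0.0163, Fisher's exact test), with atp-5 (163.7), cox-5A (112.2), cox-6A (105.2) and atp-1 (96.3) the highest. The atp-5 summit was nearer lmtr-3, and the cox-6A summit lay 854 bp from its start and 28 bp from that of the snRNA gene F54D8.7, which counts among the bound snRNA genes. Genes of DNA replication and the cell cycle were bound in 6 of 54 (odds ratio 4.10, adjusted p = 0.0163, Fisher's exact test), led by cdc-48.1 (195.0), pcn-1 (142.3), which encodes PCNA, lin-35 (120.1), the Rb homologue, and mcm-10 (III:11317199-11317518). The cdc-48.1 peak is also that of the snoRNA gene C06A1.9, which counts among the bound snoRNA genes. Chromatin and dosage compensation genes were bound in 5 of 50 (odds ratio 3.64, adjusted p = 0.0465, Fisher's exact test), led by set-2 (151.1), set-16 (113.4), lin-61 (100.7) and set-21 (85.3), which shares the peak at rpl-7A. The chromatin call was kept under 7 of 15 alternatives and in neither replicate alone. Those kept include the threshold of 0.01 and the corrected gene lists, which left this list unchanged. The replication call was kept under 12 of 15. With draws matched on promoter share its adjusted p was 0.0786 (test by random draws, ratio 3.20). With the optimal list its odds ratio was 2.36 (adjusted p = 0.190, Fisher's exact test). The replication call was also lost without replicate 1 (odds ratio 4.09). The respiratory chain call was lost without replicate 1, with a higher odds ratio (6.01, adjusted p = 0.0609, Fisher's exact test). Without replicate 2 the odds ratios were 8.04 for the respiratory chain, 7.25 for replication and 1.71 for chromatin genes. Protein-coding genes as a whole were bound in 521 of 16092 against 2.69% of other genes (odds ratio 1.21, adjusted p = 0.0163, Fisher's exact test), and mog-4, K08F11.1, tasp-1 and K01G5.10 had the highest signals. That call was kept under 11 of 14 alternatives. Without peaks nearest non-coding RNA genes, which leaves fewer other genes bound, the odds ratio was 7.01, and those of the ribosomal protein, respiratory chain, replication and chromatin lists were 11.2, 7.81, 8.33 and 7.39. By nearest start, protein-coding genes were instead under-represented, at 62.7% of passing regions against 72.5% of candidates (odds ratio 0.638, adjusted p = 1.36e-06, Fisher's exact test), a comparison chosen after seeing the data.

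Fisher's exact test takes genes as independent, although neighbouring genes share peaks, and it made false calls on simulated random sets. Drawing candidates to the same promoter share, which keeps shared peaks, gave adjusted p of 0.00176 for tRNA, snoRNA, snRNA and protein-coding genes, from the smallest p that the draws can give, 2.00e-04. By the same test by random draws the adjusted p was 0.00293 for ribosomal protein and heat shock genes and 0.00704 for spliced leader genes. With these draws it was 0.0400 for respiratory chain genes and 0.0418 for chromatin genes.

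Of the 44 lists tested, 10 were bound more often and 6 less often, and 28 did not pass. Of the 28, ncRNA genes (191 of 6420, odds ratio 1.00) passed with random draws (ratio 1.92) and GC-matched draws (1.61), not with promoter-matched draws (1.06). Among the draws, the Argonaute and small RNA list passed only with those matched on GC (5.41). At a gene distance of 2000 bp and at a global IDR of 0.001, 11 lists were bound more often. These include lists outside the 10 that are not named here. The 6 were piRNA genes (38 of 5574, odds ratio 0.191), pseudogenes (15 of 1635, 0.291), chemoreceptors (5 of 964, 0.166), F-box and MATH-BATH genes (1 of 291, 0.112), innate immunity genes (1 of 285, 0.114) and nuclear hormone receptors (1 of 230, 0.142). Their bound members included the piRNA genes 21ur-11151, 21ur-11473, 21ur-9050 and 21ur-10891 at 1 peak (142.7). Bound pseudogenes were led by WBGene00023323 (433.5), WBGene00020295 (240.5), WBGene00164983 (143.9) and WBGene00021278 (137.7), and bound chemoreceptors by srh-89 (97.1), sri-5 (86.4) and sre-23 (80.8). The chemoreceptor count also holds srpr-3 (82.6), a non-coding RNA gene that the name pattern took in. Without it and the genes of other families that the pattern took in, a correction made after seeing the data, 4 of 950 were bound (odds ratio 0.134). Single bound members were fbxb-58 (114.3), clec-104 (80.3) and nhr-239 (71.3). When candidates were drawn at random to the same promoter share, only piRNA genes, pseudogenes and chemoreceptors stayed past the threshold (adjusted p = 0.00176, 0.00293 and 0.00293, permutation by draws), and with random or GC-matched draws none of the 6 did (0 lists). The ratios of bound to drawn genes were then 0.530 and 0.709 for piRNA genes, 0.623 and 0.624 for pseudogenes, and 0.368 and 0.496 for chemoreceptors. The 38 piRNA genes came from 14 peaks. The pseudogene call was lost without replicate 2 (odds ratio 0.482, adjusted p = 0.0849) and at a global IDR of 0.001 (0.460, adjusted p = 0.0667), by Fisher's exact test. In neither replicate alone did the F-box, innate immunity and nuclear hormone receptor lists pass, with odds ratios of 0.540, 0.280 and 0.669 without replicate 1 and 0 without replicate 2. Chemoreceptors had 0.0829 and 0 in these settings, and piRNA genes 0.118 without replicate 2.

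Lists of muscle (1 of 42), intestine (0 of 30), pharynx (0 of 24), epidermis (0 of 40), pan-neuronal (3 of 33) and germline (5 of 60) genes did not pass, the germline list at an adjusted p of 0.0804 by Fisher's exact test.

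**Figure D2:**
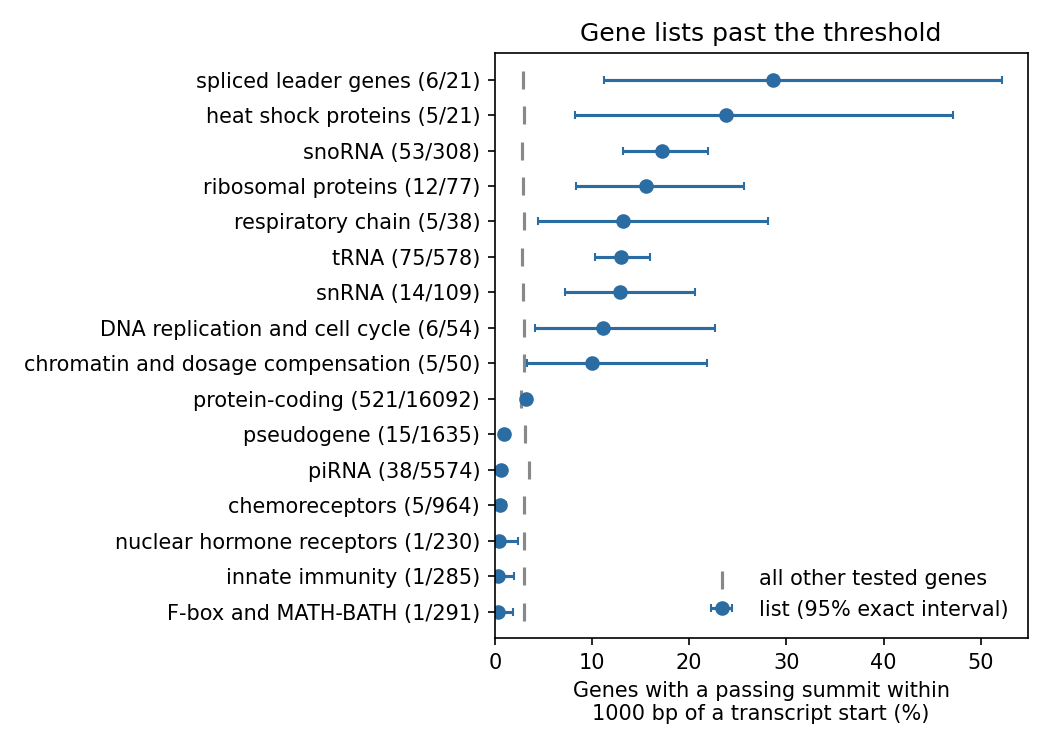
Percentage of genes with a passing summit within 1000 bp of a transcript start, for the 16 gene lists past the threshold (points, with exact 95% intervals; bound and tested genes in brackets) and for all other tested genes (grey ticks). Spliced leader genes, heat shock proteins and snoRNA genes had the highest shares, and piRNA genes and chemoreceptors lay below the other genes.

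Among words more frequent at passing summits than at matched candidates, most of those with the smallest p contained CG. Words with CG were not tested as a class. Of the 2080 6-mers, 192 were more frequent and 151 less frequent. The word ACGCGC was in 14.3% of the 566 windows against 4.35% of 5607 matched windows (odds ratio 3.67, adjusted p = 9.95e-15, Fisher's exact test). The word GTACAC was in 11.0% against 3.12% (odds ratio 3.82, adjusted p = 2.63e-12, Fisher's exact test). Of the 20 words with the smallest p, 16 contained CG. Median GC content of the windows was 50.5% in passing regions, 40.6% in all candidates and 50.5% in the matched ones. With the list of replicate 1 alone 124 words were more frequent, and with that of replicate 2 alone 81, from fewer windows. Of these, 98 and 67 were among the 192. Without peaks whose sequence recurs, 133 words passed, 109 of them shared, and against shuffled sequences 151, with 98 shared. The words GTACAC, CACGGC, ACGGCC and GGCCGA lie within AGGAGTACACGGCCGA, a sequence that 3 regions with similar sequence share.

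Promoter regions had a higher signal than other regions, with medians of 91.3 (402 regions) and 80.4 (164 regions). The log2 difference was 0.18 (permutation test, adjusted p = 6.00e-05). It was 0.12 with either replicate's list alone (adjusted p = 0.121 and 0.174, permutation test) and -0.039 at a global IDR of 0.001. In replicate 2's own signal it was 0.060 (adjusted p = 0.259, permutation test). Regions whose nearest start, within 1000 bp, was that of a non-coding RNA gene (174 regions) had a median of 87.2 against 88.5 elsewhere, a log2 difference of -0.022 (permutation test, adjusted p = 0.742). It passed at a global IDR of 0.001 (-0.25, adjusted p = 9.00e-04, permutation test) and without replicate 1 (-0.20, adjusted p = 0.0104, permutation test).

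The replicate lists shared 136 of the 238 peaks of replicate 1 (57.1%, 95% interval 50.6 to 63.5) and 137 of the 256 of replicate 2 (53.5%, 47.2 to 59.8), with an overlap of at least 1 base. Of the peaks of replicates 1 and 2, 91.2% and 84.0% overlapped the conservative list. Over the 562 passing regions with signal in both replicates, Spearman's rho was 0.407 (bootstrap 95% interval 0.326 to 0.483) and Pearson's r of log2 signal was 0.667. These are correlations across regions, which are not independent replicates, and regions were selected for reproducibility. The median log2 ratio of replicate 2 to replicate 1 was 0.17 (0.12 to 0.22), with an SD of 0.44 across regions.

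Regions with the highest ratio to replicate 2 were at the snoRNA C53B7.8 (X:6867734-6868053, log2 ratio 1.68), at drr-2 and its divergent neighbour set-16 (III:13643583-13643902, 1.64) and at iff-2, a translation factor gene, with F54C9.14 divergent (II:8561279-8561598, 1.34). The lowest were at C26B2.7 (IV:8015661-8015980, -1.32), at ecps-1 with atx-2 divergent (III:10460595-10460914, -1.03) and at sls-2.8 with tim-1 divergent (III:12250263-12250582, -0.93). With 2 samples no test between them was possible.

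**Figure D3:**
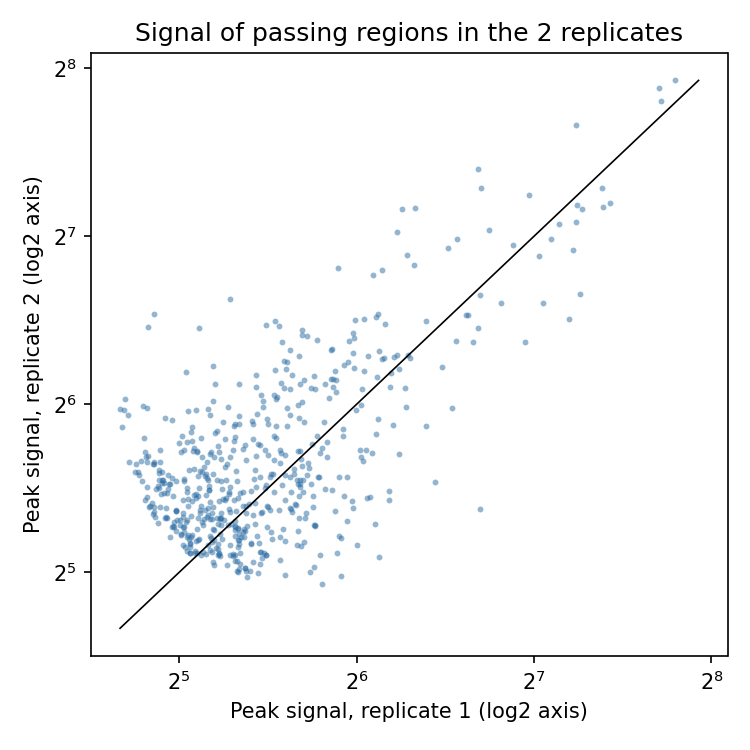
Signal of each passing region in replicate 1 (x axis) and replicate 2 (y axis), both on log2 axes, with the line of equal signal. Over 562 regions Spearman's rho was 0.407, and 362 regions lay above the line.

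At the tagged gene bed-2 (WBGene00012943, III:11463665-11470808, minus strand), with 2000 bp on each side, no thresholded list held a peak (0 in each of the 4). The ranked list of true replicates held 17 candidates there. The strongest, III:11464866-11465185, had a signal of 52.2 and an IDR score of 359 against the 830 of the threshold, and was number 2058 of 82301 by signal. In the replicates' own ranked lists the highest signals at the locus were 30.4 and 39.2.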

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

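In the ranked list of true replicates, 21 peaks had a score at or above the threshold and overlapped no peak of the conservative list. They were singled out because they score above the threshold and entered neither the passing regions nor the background candidates. The strongest peak of the whole list was among them, at X:15810950-15811269 with a signal of 937.3, more than any peak kept. The nearest start is that of the pseudogene WBGene00044155, 857 bp away. Another lay 278 bp from the start of the 5S rRNA gene rrn-4.2 (V:17127966-17128285, signal 131.7). For further peaks the nearest starts were those of the non-coding RNA genes K01F9.6 (signal 199.3) and Y95D11A.4 (193.1), at 2090 bp and 1880 bp. Of the 21, 90.5% had another copy of the summit window in the genome, against 31.8% of passing regions (odds ratio 20.4, p = 6.72e-08, Fisher's exact test). It took these peaks as independent, although some lie close together, such as V:7920929-7921248 and V:7922530-7922849. Passing regions, in contrast, were merged. Removal of regions of repeated sequence by the authors is a candidate explanation, since the thresholded lists derive from 1 further file that was not analysed here. The test shows the repeats and not the step that removed the peaks. No biological explanation was tested, since the design has 1 group.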

How the results depend on the processing

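The promoter odds ratio (3.43 to 8.37) and the distance difference (-811.5 to -420 bp) kept direction and threshold under all alternatives run, as did the ribosomal protein and heat shock lists (15 alternatives) and snoRNA genes (14). The cause of the other changes was not tested, except where stated. The threshold of 0.001, multi-copy, GC-matched and promoter-matched settings, protein-coding genes or starts only, corrected gene lists, the next 2000 candidates, bed-2 in the optimal list, and the peak and bed-2 counts with 1 replicate were chosen after seeing the data. The deposited lists already end at 0.01, so that setting changed nothing. Counts of alternatives include it. They also include the corrected gene lists, which changed the members of the ribosomal protein and chemoreceptor lists only.

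With each replicate alone, peaks numbered 238 to 256, enriched 6-mers 81 to 124 and depleted 6-mers 25 to 51, from fewer regions, and lists bound less often 3 for each. The promoter signal difference was 0.12 to 0.12 and no longer passed, the non-coding RNA one -0.20 to -0.13, passing without replicate 1, and the intergenic odds ratio 0.895 to 1.07. At 0.001, peaks numbered 194, enriched 6-mers 106, depleted 28, lists bound less often 3, chromosomes past the threshold 1, rho 0.488, the promoter signal difference -0.039 and the non-coding RNA one -0.25, now past the threshold. Unmerged peaks gave 1 chromosome. Over all ranked peaks, unmerged and with the matched-peak signal of the ranked list in place of each replicate's own list, rho was 0.199. In replicate 2's signal the promoter difference was 0.060.

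Lists bound less often numbered 3 with the optimal list, 3 with promoter-matched draws, 3 without multi-copy peaks, and 0 with random or GC-matched draws, and the number bound more often was 4 among protein-coding genes, where small RNA lists cannot enter. Depleted words numbered 81 without multi-copy peaks, 319 in windows of 100 bp and 1 for 8-mers. Leaving out peaks whose nearest start within 1000 bp is of a non-coding RNA gene takes out, by construction, the peaks nearest to small RNA genes. No bound tRNA or spliced leader gene was then left, and most bound snRNA genes were lost (odds ratios 0, 0 and 0.609). For snoRNA genes the odds ratio was then 2.71. Without multi-copy peaks the snRNA odds ratio was 0.878. Read depth is unknown, so its effect on these counts could not be examined.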

Other observations

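Passing summits lay on the upstream side of genes. Of 377 regions within 1000 bp of the nearest protein-coding start, 300 (79.6%, 95% interval 75.2 to 83.5) had the summit upstream, against 42.3% of candidates (odds ratio 5.32, p = 8.50e-49, Fisher's exact test). The nearest start was that of a tRNA gene for 45 regions, a snoRNA gene for 38 and an snRNA gene for 11. These tests, the sequence families below and the comparison of ribosomal protein with somatic genes were chosen after seeing the data.

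Several of the strongest regions share blocks of sequence. Linking windows of 201 bp by similarity gave 15 families of at least 4 regions, holding 109 of the 566 regions and 14 of the 25 strongest. A family of 18 regions included those at eel-1, dnj-28, rps-24 and atad-3, and 16 of its windows hold AGGCCCCACGAAAAGG. A family of 11 regions included that at mog-4, and all 11 hold CGTTGAATATTCAGTC. Each region of another family, of 4 regions, lay close to a region of this family, as at II:4049720-4050039 and II:4047993-4048147. The families are therefore not all separate elements. Median signal was 101.2 in families and 85.8 elsewhere, a log2 difference of 0.24 (permutation p = 3.00e-05). The test took regions as independent, although members of a family share sequence. Medians of single families ran from 77.7 to 230.7, so the difference did not hold for every family.

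The first technical explanation weighed for summit sequences that recur in the genome was that peaks form at every copy of a repeated element. Of the 967 genomic copies of the families, 124 (12.8%) lay within 200 bp of a passing summit (bootstrap 95% interval over families 6.37 to 25.1). The bootstrap took families as independent. The copies include the 109 family regions themselves, which lie near a passing summit by construction, so the share among other copies was lower. With those regions counted, 63.2% of copies lay near a ranked candidate of any score, and the share at random positions was not measured. The share near a passing summit was 19.97% without the family of 371 copies and ran from 1.35% to 56.3% over families. These shares argue against passing peaks at every copy of these families. The interval reached the lower bound set in advance, and weaker peaks at most copies stay open. GC content stays open as a possible explanation of how often windows recur, since 31.8% of passing windows and 28.9% of matched candidates had another copy (odds ratio 1.15, 95% interval 0.946 to 1.38, Fisher's exact test). Candidates not matched on GC content were not searched, so no excess of recurrence over them was shown. Reads shared between near-identical copies cannot be told apart from other causes, because 36.7% of the multi-copy windows had such a copy, between the bounds set in advance, and no biological explanation was tested, since the design has 1 group.

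Binding at ribosomal protein, snoRNA and tRNA genes was weighed in the same way. Against candidates matched on GC content, the lowest of the 3 ratios of bound to drawn genes was 4.25, which argues against GC content as the whole cause. Ribosomal protein genes were bound more often than vitellogenin, cuticle collagen and body wall muscle genes, 12 of 77 against 4 of 210 (odds ratio 9.51, p = 4.83e-05, Fisher's exact test), but no expression was measured, so transcription in somatic tissue drawing signal at any gene stays open. Signal that any tagged protein shows at such promoters was not tested, since no other target was analysed here. Binding of BED-2 itself at these promoters therefore remains a hypothesis.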
